A study of Mus musculus with 24 samples.

How the data were processed

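The series holds 24 Affymetrix Murine Genome U74Av2 arrays of mouse adipocytes grown in primary culture from brown or white fat. Per the labels, the cells were collected at day 4, which the labels call not differentiated, or at day 7, which they call differentiated. Total RNA was extracted with Trizol, and biotin-labelled cRNA was made in a single round from 5 ug of RNA, per the labels' protocols. The groups were brown day 4 (n = 5 arrays), brown day 7 (n = 5), white day 4 (n = 8) and white day 7 (n = 6), taken from the array labels. Arrays are named here by their group and the number in their label. No label says whether the arrays of a group came from separate animals or cultures, so every p-value measures only the spread between these arrays, which may be technical. The numbers of the brown arrays all precede those of the white arrays, and the labels do not say what the numbers stand for, so a difference in handling between the cell types cannot be separated from the cell type.

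The values deposited by the authors are probe set signal intensities on a linear scale for 12488 probe sets, with no detection calls used here. They were made with MAS5, per the submitters' processing notes, whose version is not given in the sources used here. The 2% trimmed mean of every array lay close to 150, so that the common scale had already been set before deposit. Median signal per array ran from 41.9 to 59.0. Arrays carry no count depth, and their number limits the precision. MAS5 subtracts mismatch signal, so values near background are noisy. Each array was brought to a 2% trimmed mean of 150 exactly, values under the 20th percentile of all values (a signal of 8.22) were set to that floor, and log2 was taken. Probe sets were kept when they lay above the 40th percentile of their own array on at least 5 arrays, and the 66 control probe sets were left out. That left 8397 probe sets, of whose values 1.56% lay at the floor. A gene whose probe set was at the floor on every array of one group is given as "at least" the fold between the other group and the floor. Where only some arrays of a group lay at the floor, the size of a difference depends on the floor.

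Gene symbols came from the platform annotation, which can be old. It gives 1 symbol for 10855 probe sets, several for 396 and none for 1237. By gene identifier, 10839 of the first were matched to the reference gene table, which changed 0 symbols. Probe sets with several symbols or none were counted and never named. A gene was represented by its tested probe set with the highest mean signal, which gave 6281 genes. No genome build was named in the sources used here, and no positions are given. Probe sets whose names carry the suffix for related sequences, among them those of Hoxc9, Tie1, Sox18, Tnnc2 and Actc1, may also bind transcripts of the same gene family.

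The 4 group means were fitted together with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, so that all groups shared one estimate of the spread with 20 residual degrees of freedom. The contrasts were day 7 against day 4 in brown and in white cells, brown against white at day 4 and at day 7, and the difference of the day 7 against day 4 changes (brown minus white). Tests were two-sided. Adjusted p-values follow Benjamini and Hochberg over all 8397 probe sets within a contrast, with a threshold of 0.05. Values after ± are standard errors of the fit unless SD is written. Calls shared by comparisons without common arrays were set against the product of the shares called, with Fisher's exact test.

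For gene lists, camera (limma) was run on the 6281 genes with its preset inter-gene correlation of 0.01 and adjusted over the 24 lists within a contrast. It was repeated with an estimated correlation and with fry. With the estimated correlation, 2 of 50 list calls held: the white-associated and the striated muscle lists in brown against white at day 4. Both lists hold genes already reported from this study, so these 2 calls are not independent evidence. By fry, which does not set a list against the genes outside it, 42 of the 50 held. The lists, fixed before the data were examined, were adipocyte core, thermogenic, white-associated, myogenic regulators, striated muscle structure, smooth muscle and pericyte, developmental patterning, oxidative phosphorylation, TCA cycle, fatty acid oxidation, lipid synthesis, cholesterol synthesis, cell cycle, extracellular matrix, Wnt, BMP and TGF-beta signalling, glycolysis, interferon response, macrophage, lymphocyte, erythrocyte, endothelial, neural and Schwann cell, mesothelial and epithelial, and cartilage and bone. Some lists share tested members: 8 adipocyte core, 7 white-associated, 5 oxidative phosphorylation, 5 lipid synthesis, 4 TCA cycle, 4 developmental patterning, 1 thermogenic, 1 extracellular matrix and 1 mesothelial member stand in another list. A member count is given over all probe sets tested and, in a second form, adjusted over the list alone.

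The design, the lists, the alternatives tried and the rule for the genes named were also fixed before the data were examined. The rule takes, for each comparison of 2 groups, the 10 genes with the highest and the 10 with the lowest log2 difference among those past the threshold whose arrays did not overlap between groups; for the difference of changes, the 5 highest and 5 lowest past the threshold; up to 4 members of each list past the threshold with the largest difference, or the 2 with the smallest p where none passed; and a panel of Ucp1, Cidea, Ppargc1a, Prdm16, Dio2, Pparg, Cebpa, Fabp4, Adipoq, Lep, Myod1, Myog, Myf5, Zic1, Lhx8, Tcf21, Hoxc9 and Dpt. Other genes are named with the words that they were chosen after their values were seen. Ucp1, Ppargc1a, Dio2 and Myf5 did not pass the filter and were not tested. No probe set on the array had Prdm16 as its single symbol, so that gene was not analysed here.

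RNA quality was followed by the 3' over 5' signal ratio of the Gapdh and actin control probe sets, compared between groups by exact two-sided permutation tests (SciPy 1.17.1, Python 3.11.15), adjusted over 16 tests. Figures were drawn with matplotlib 3.10.9. The alternatives were quantile normalization, no floor (signals under 1 set to 1), a floor at the 40th percentile, no filter, a filter at the 60th percentile, only the groups compared in the fit, eBayes without trend, array weights, runs of adjacent array numbers as a random block (consensus correlation 0.245), a fold of at least 2, the mean of all probe sets of a gene and each array left out in turn. The Gapdh ratio as a covariate and the removal of white day 4 arrays 45 and 51 were added after seeing the data.

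The fit was tested on simulated data with known changes in 8397 probe sets. Each probe set had its real overall mean and pooled spread, with noise drawn independently for every array. Differences in spread between groups, outlying arrays and correlation between arrays or probe sets were not simulated. Far fewer probe sets were changed than were called in the real data, so the rates may not hold there. For log2 changes of 0.5, 1 and 2 the fit recovered 11.9%, 65.7% and 98.5% in the comparison of brown day 7 with day 4, with 3.31% false calls. In white day 7 against day 4 it recovered 19.4%, 77.6% and 97.0%, with 7.86% false calls. In brown against white it recovered 17.9%, 80.6% and 97.0% at day 4, with 5.11% false calls, and 16.4%, 65.7% and 97.0% at day 7, with 6.30% false calls. The list test, on 6281 genes drawn independently of each other, called 3 of 3 shifted lists and 0 of 20 unshifted lists in each of these comparisons.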

Results

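Gene expression was measured in brown and white mouse fat cells in primary culture at day 4 and at day 7, to compare pre- and mature adipocytes of each kind. One array was used per sample, with 5 brown day 4, 5 brown day 7, 8 white day 4 and 6 white day 7 arrays. Brown fat burns lipid for heat through the uncoupling protein Ucp1, and white fat stores it. Median signal per array was 41.9 to 59.0. Correlations between arrays of a group ran from 0.890 (white day 4) to 0.964 (brown day 7). The first principal component, with 30% of the variance, set brown arrays apart from white arrays other than white day 4 arrays 45 and 51, which lay between them. On the second, with 15.3%, every day 7 array lay above every day 4 array of its own cell type.

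**Figure D1:**
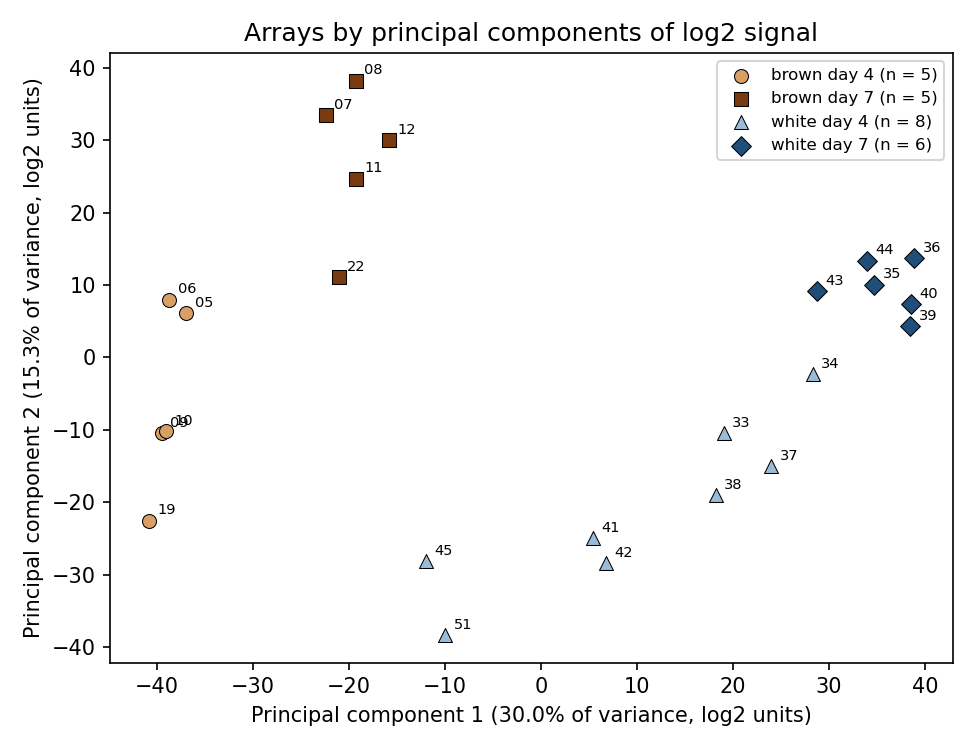
Each point is 1 of the 24 arrays, placed by its first (30% of the variance) and second (15.3%) principal components of log2 signal, in log2 units, with its number and its group by colour and shape. White day 4 arrays 45 and 51, at -12 and -9.97 on the first component, sit apart from the other 6 arrays of their group, at 5.41 to 28.3.

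The white day 7 arrays carried a sign of lower RNA integrity. Their 3' over 5' signal ratio of Gapdh, which grows as RNA is degraded from the 5' end, averaged 1.36 ± 0.204 (SD, n = 6), against 0.943 ± 0.0955 (SD, n = 8) at white day 4 (exact permutation p = 0.00133, adjusted 0.0107). In brown cells the ratio was 0.884 ± 0.0825 (SD, n = 5) at day 4 and 0.889 ± 0.0379 (SD, n = 5) at day 7, and brown and white differed at day 7 (exact permutation p = 0.00433, adjusted 0.0173). Brown and white did not differ detectably at day 4 (exact permutation p = 0.277, adjusted 0.392). The actin ratio was 2.38 ± 0.296 (SD, n = 6) at white day 7 and 1.56 ± 0.186 (SD, n = 8) at white day 4 (exact permutation p = 0.000666, adjusted 0.0107). Every white day 7 group mean below therefore stands on arrays with this higher ratio.

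**Figure D2:**
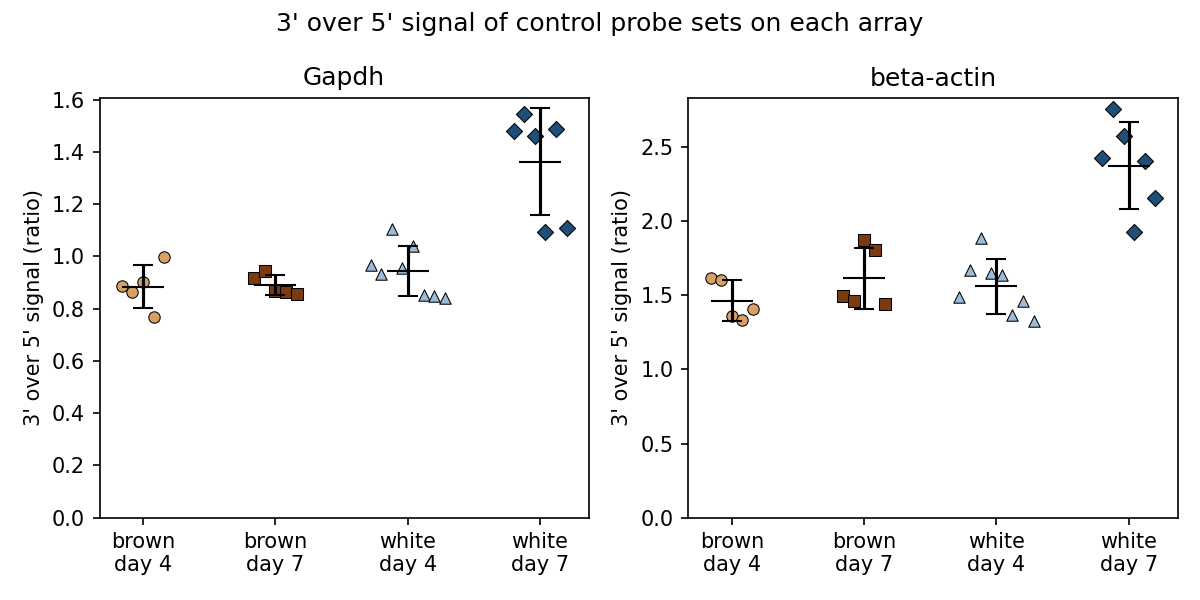
The 3' over 5' signal ratio of the Gapdh and beta-actin control probe sets is plotted for each array by group, with the mean and SD as lines. The Gapdh ratio of the 6 white day 7 arrays averaged 1.36, and the other group means lay between 0.884 and 0.943.

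In brown cells, 13 of 32 adipocyte core genes and 12 of 21 fatty acid oxidation genes were higher at day 7 than at day 4 (camera adjusted p = 1.71e-08 for each), and 21 of 39 cell cycle genes were lower (adjusted p = 1.36e-17). With an estimated correlation the adjusted p was 0.280, 0.188 and 0.188. Retn, which encodes the hormone resistin, rose by 4.36 ± 0.73 on the log2 scale, and Thrsp, a regulator of lipid synthesis, by 3.42 ± 0.48. Cox8b, a subunit isoform of cytochrome c oxidase found in brown fat and muscle, rose by 2.68 ± 0.44, and Igf1, a growth factor, by 2.79 ± 0.47. The thymidine kinase Tk1 fell by 1.89 ± 0.24, the mitotic kinase Aurka by 1.82 ± 0.33 and the mitotic regulator Cdc20 by 1.65 ± 0.30. In all, 1013 of 8397 probe sets changed, 504 higher and 509 lower, or 816 of 6281 genes. Of the probe sets, 336 changed at least 2-fold, 237 of them higher and 99 lower. The count was 668 without brown day 7 array 08 and 1666 with array weights. For 816 of the 8397 probe sets, 595 of them changed, the 5 day 7 and 5 day 4 arrays did not overlap, where chance gives 0.794%.

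The rankings of rises and falls here cover only genes past the threshold whose day 7 and day 4 arrays did not overlap. The other genes with the largest rises in brown cells were Mmp3, a matrix metalloproteinase, at 3.10 ± 0.48, the carboxylesterase Ces1d at 2.94 ± 0.57, Gm4788 at 2.61 ± 0.40 and the plasma protein Orm1 at 2.49 ± 0.58, with adjusted p at most 0.00497. Ahsg, which encodes the plasma protein fetuin-A, rose at least 7.13-fold and Fam167b at least 6.99-fold, from the floor on all day 4 arrays. Some day 4 arrays also lay at the floor for Retn (2 of 5), Ces1d (3), Gm4788 (2), Igf1 (1) and Orm1 (1), so that the sizes of these rises depend on the floor. The largest falls included the histone chaperone Asf1b at -1.99 ± 0.36, the kinesin Kifc1 at -1.98 ± 0.44 (-1.24 with the floor at the 40th percentile), Rbm14 at -1.69 ± 0.28, S100a4 at -1.58 ± 0.26, H1f10 at -1.57 ± 0.39 and Rrm2, a ribonucleotide reductase subunit, at -1.55 ± 0.28. Mcm10, a replication factor, fell by 1.63 ± 0.38, a call that ended with the floor at the 40th percentile (adjusted p = 0.109). Of the fixed panel, the myogenic factor Myog fell by 1.72 ± 0.35 (adjusted p = 0.00186). Cidea, a lipid droplet protein abundant in brown fat, rose by 2.29 ± 0.63 (adjusted p = 0.0165). The Cidea call ended without brown day 4 array 09 or 10 or brown day 7 array 07 or 08 (adjusted p = 0.0702, 0.0630, 0.0563 and 0.0722), and with only the brown arrays in the fit (0.0904). By runs of adjacent array numbers, Cidea signal was 378 and 182 on day 4 arrays 05 and 06 against 1084 and 1755 on day 7 arrays 07 and 08. It was 27.4 and 32.7 on arrays 09 and 10 against 160 and 472 on arrays 11 and 12. Adipoq, which encodes adiponectin, rose by 1.18 ± 0.32 (adjusted p = 0.0145; 0.0635 without brown day 4 array 09), and Dpt by 1.19 ± 0.32 (adjusted p = 0.0157; 0.0532 without brown day 4 array 19). Pparg, the master regulator of adipogenesis, measured 0.37 ± 0.23, Cebpa -0.31 ± 0.23, Fabp4 0.25 ± 0.20, Lep 0.21 ± 0.26, Zic1 -0.41 ± 0.24, Lhx8 -0.14 ± 0.34, Tcf21 -0.32 ± 0.24, Hoxc9 0.33 ± 0.24 and Myod1 -0.55 ± 0.19, and none of these passed.

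By list, 13 of 32 adipocyte core genes rose in brown cells and 1 fell (camera adjusted p = 1.71e-08; 19 and 1 adjusted over the list alone), with adjusted p = 0.280 with an estimated correlation. Besides Retn and Thrsp, Adig rose by 2.28 ± 0.38. In the thermogenic list 5 of 12 genes rose (adjusted p = 0.0141; 5 higher and 1 lower adjusted over the list alone), and adjusted p = 0.280 with an estimated correlation. They included Cox8b, the cytochrome c oxidase isoform gene Cox7a1 at 2.53 ± 0.55 and the fatty acid carrier Fabp3 at 1.85 ± 0.46. Fatty acid oxidation genes rose in 12 of 21 cases (adjusted p = 1.71e-08; 15 adjusted over the list alone, with adjusted p = 0.188 with an estimated correlation). The dehydrogenase Acadm at 1.72 ± 0.31 and Hadhb at 1.18 ± 0.20 were among them. Of oxidative phosphorylation genes 11 of 58 rose (adjusted p = 1.26e-06; 12 adjusted over the list alone, with adjusted p = 0.3998 with an estimated correlation). Etfdh at 1.26 ± 0.29 was among them. Of TCA cycle genes 6 of 20 rose (adjusted p = 2.54e-06; 12 adjusted over the list alone, with adjusted p = 0.280 with an estimated correlation). Sucla2 at 1.08 ± 0.24 was among them. Of lipid synthesis genes 6 of 14 rose (adjusted p = 7.38e-05; 8 adjusted over the list alone, with adjusted p = 0.280 with an estimated correlation). Lpin1 at 1.59 ± 0.26 and the fatty acid synthase gene Fasn at 1.18 ± 0.25 were among them. Of cell cycle genes 21 of 39 fell and 0 rose (adjusted p = 1.36e-17; 26 adjusted over the list alone, with adjusted p = 0.188 with an estimated correlation).

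In the extracellular matrix list 14 of 43 genes rose in brown cells (adjusted p = 2.31e-07; 16 adjusted over the list alone, with adjusted p = 0.283 with an estimated correlation). Thbs2 at 2.21 ± 0.32, Lum at 1.54 ± 0.34 and Dcn at 1.34 ± 0.26 were among them. Of smooth muscle and pericyte genes 5 of 12 rose (adjusted p = 0.000115; 6 adjusted over the list alone, with adjusted p = 0.188 with an estimated correlation). The potassium channel subunit Abcc9 at 1.86 ± 0.27 and Mcam at 1.13 ± 0.19 were among them. Striated muscle genes did not pass as a list (1 of 30 higher and 3 lower, adjusted p = 0.0527; 1 and 7 adjusted over the list alone). Among them the skeletal actin gene Acta1 fell by 1.55 ± 0.32 and the myoglobin gene Mb, at the floor on 1 of 5 day 4 arrays, rose by 1.90 ± 0.46. The other 14 lists did not pass, with adjusted p from 0.0978 (endothelial, 2 higher and 1 lower of 11) to 0.969. The median, mean and test differed in sign for the myogenic regulators, the interferon response and the Wnt, BMP and TGF-beta signalling lists.

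In white cells, 18 of 32 adipocyte core genes and 8 of 14 lipid synthesis genes were higher at day 7 than at day 4 (camera adjusted p = 2.63e-08 and 3.41e-07), and 24 of 39 cell cycle genes were lower (adjusted p = 7.85e-13). With an estimated correlation the adjusted p was 0.414 for each. Thrsp rose by 3.61 ± 0.41, the complement protease gene Cfi by 3.33 ± 0.46, Orm1 by 3.13 ± 0.49 and the smooth muscle myosin gene Myh11 by 3.01 ± 0.36. The amylase gene Amy1 rose by 3.03 ± 0.30, Cdo1, which breaks down cysteine, by 2.67 ± 0.30, and the fatty acid transporter gene Slc27a1 by 2.55 ± 0.37. The replication helicase subunits Mcm5 and Mcm7 fell by 1.62 ± 0.23 and 1.36 ± 0.19, and Tk1 by 1.47 ± 0.20. In all, 1595 of 8397 probe sets changed, 702 higher and 893 lower, or 1223 of 6281 genes; 328 changed at least 2-fold (203 higher, 125 lower). For 402 of the 8397, 393 of them changed, the 6 day 7 and 8 day 4 arrays did not overlap, where chance gives 0.0666%. The Gapdh 3' over 5' ratio, 1.36 at day 7 and 0.943 at day 4, moved with this comparison, and with the ratio as a covariate, chosen after seeing the data, 37 probe sets passed. Of the 78 genes past the threshold that the rule named here, 9 passed in that fit, among them Amy1, Cdo1, Mcm5, Mcm7 and Tk1. The size with the ratio was a median 0.880 times that without it across the 78, at most 0.5 times for 11 of them, and turned for 2, Nsdhl and Mvd. The median standard error was 0.255 without and 0.423 with it. Thrsp, Cfi, Orm1, Myh11 and Slc27a1 lost their calls at 2.85, 2.68, 2.99, 2.66 and 2.07 (adjusted p = 0.0556, 0.119, 0.108, 0.0507 and 0.133). The count was 1054 without arrays 45 and 51.

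Among genes past the threshold whose arrays did not overlap between days, the remaining largest rises in white cells were Wfdc18 at 2.37 ± 0.51, Lrg1 at 2.17 ± 0.38 and Anxa8 at 2.06 ± 0.43. Of the 8 day 4 arrays, 5 lay at the floor for Amy1, 2 for Orm1, 2 for Wfdc18, 1 for Cfi and 1 for Anxa8, and of the 6 day 7 arrays 2 for Prim2 and 1 for Kcnd1. The sizes of these changes depend on the floor, and that of Amy1 was 3.34 with no floor and 1.56 with the floor at the 40th percentile. Among genes whose arrays did not overlap between days, the remaining largest falls were Kcnd1 at -1.45 ± 0.35, the class I histocompatibility gene H2-M10.1 at -1.44 ± 0.26, Ube2l6 at -1.42 ± 0.22, S100a4 at -1.38 ± 0.22, the primase subunit gene Prim2 at -1.37 ± 0.38 and Pdia6 at -1.33 ± 0.17. St6galnac6 fell at least 4.69-fold, to the floor on all day 7 arrays, a call that ended with the floor at the 40th percentile (adjusted p = 0.0674). The Prim2 call ended without white day 7 array 36 (adjusted p = 0.0511). With the Gapdh ratio as a covariate St6galnac6, Ube2l6 and Pdia6 shrank to -1.32, -0.87 and -0.76 and lost their calls (adjusted p = 0.524, 0.287 and 0.181), and H2-M10.1 grew to -2.18 and kept its call (0.0125). Calls were also lost by Wfdc18, Lrg1 and Anxa8 at 2.03, 2.55 and 1.49 (0.328, 0.0713 and 0.405) and by Kcnd1, S100a4 and Prim2 at -1.51, -1.28 and -1.48 (0.276, 0.131 and 0.354). Of the panel, Adipoq rose by 1.59 ± 0.27 (adjusted p = 0.000378) and Dpt by 1.19 ± 0.28 (adjusted p = 0.00393). Pparg rose by 0.63 ± 0.19 (adjusted p = 0.0239), and missed the threshold without white day 4 array 45 or white day 7 array 43 or 44 (adjusted p = 0.0503, 0.0669 and 0.06005), without arrays 45 and 51 together (0.115) and with only the white arrays in the fit (0.0621). With the covariate Adipoq, Dpt and Pparg measured 1.29, 0.81 and 0.27 and lost their calls (adjusted p = 0.212, 0.518 and 0.813). Cebpa measured 0.11 ± 0.19, Fabp4 0.40 ± 0.17, Lep 0.01 ± 0.22, Cidea -0.22 ± 0.54, Myog 0.05 ± 0.30, Myod1 -0.11 ± 0.17, Lhx8 -0.02 ± 0.29, Tcf21 -0.05 ± 0.21 and Hoxc9 -0.21 ± 0.20, and none passed. Zic1 was at the floor on all white arrays.

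Of adipocyte core genes 18 of 32 rose in white cells and 1 fell (camera adjusted p = 2.63e-08; 21 and 2 adjusted over the list alone, with adjusted p = 0.414 with an estimated correlation). Retn at 2.56 ± 0.62, the lipid droplet genes Cidec at 2.15 ± 0.48 and Plin4 at 1.90 ± 0.33 were among them. Of lipid synthesis genes 8 of 14 rose (adjusted p = 3.41e-07; 10 adjusted over the list alone, with adjusted p = 0.414 with an estimated correlation). Fasn at 1.65 ± 0.22 and the malic enzyme gene Me1 at 1.51 ± 0.22 were among them. Of fatty acid oxidation genes 8 of 21 rose (adjusted p = 4.00e-05; 11 higher and 1 lower adjusted over the list alone, with adjusted p = 0.414 with an estimated correlation). Acadm at 1.67 ± 0.26 was among them. Of cell cycle genes 24 of 39 fell and 0 rose (adjusted p = 7.85e-13; 25 adjusted over the list alone, with adjusted p = 0.414 with an estimated correlation). Cdc20 at -1.52 ± 0.25 was among them. Of extracellular matrix genes 13 of 43 rose and 2 fell (adjusted p = 4.00e-05; 19 and 2 adjusted over the list alone, with adjusted p = 0.640 with an estimated correlation). Thbs2 at 1.85 ± 0.28, Lum at 1.56 ± 0.29 and Vcan at -1.61 ± 0.40 (-1.04 with the floor at the 40th percentile) were among them. Of smooth muscle and pericyte genes 3 of 12 rose (adjusted p = 0.0206; 3 adjusted over the list alone, with adjusted p = 0.414 with an estimated correlation), a list call that ended with the Gapdh ratio as a covariate (adjusted p = 0.191). Of TCA cycle genes 7 of 20 rose and 1 fell (adjusted p = 0.0302; 7 and 1 adjusted over the list alone, with adjusted p = 0.762 with an estimated correlation). Pcx, which encodes pyruvate carboxylase, rose by 1.40 ± 0.24. That list call ended with the covariate (adjusted p = 0.290), with the mean of probe sets (0.0787), by fry (0.156) and without any 1 of white day 4 arrays 33, 34, 37 and 38 (adjusted p = 0.0542, 0.0765, 0.0645 and 0.0511) or white day 7 arrays 43 and 44 (0.146 and 0.117).

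White day 4 arrays 45 and 51 had adipocyte core means of 8.16 and 7.78 (log2 signal), against 8.46 to 9.17 on the other 6 arrays of their group. Their lipid synthesis means were 9.19 and 8.80 (others 9.43 to 9.74), their extracellular matrix means 9.05 and 8.81 (others 9.20 to 9.86) and their fatty acid oxidation means 8.12 and 8.14 (others 8.20 to 8.49). These 2 arrays thus lower the day 4 means from which the 4 lists rose in white cells. Without them the 4 lists still passed (camera adjusted p = 3.01e-08, 1.26e-07, 0.00088 and 3.69e-06). In the fit with the Gapdh ratio Retn, Cidec, Plin4, Fasn, Me1 and Acadm lost their calls at 3.31, 1.999, 1.28, 1.16, 1.26 and 1.26 (adjusted p = 0.151, 0.302, 0.315, 0.133, 0.116 and 0.199). So did Thbs2, Lum, Vcan and Pcx at 1.93, 1.57, -2.38 and 1.11 (0.0661, 0.151, 0.103 and 0.216).

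Macrophage markers also moved with the day in white cells. Of 14 markers 3 rose (adjusted p = 0.0302; 5 adjusted over the list alone, with adjusted p = 0.730 with an estimated correlation), and the lysozyme gene Lyz2 rose by 2.24 ± 0.41, a call lost at 2.57 with the Gapdh ratio as a covariate (0.0924). The macrophage call ended without any 1 of 9 single arrays, with the highest adjusted p, 0.127, without white day 7 array 40, and also without white day 4 arrays 33, 37, 38 and 41 and white day 7 arrays 35, 36, 39 and 44 (0.0799, 0.0645, 0.0580, 0.0684, 0.102, 0.127, 0.0877 and 0.0551). It also ended with the stricter filter (0.276), with no filter (0.0734) and by fry (0.119). Lyz2 rose by 2.21 ± 0.48 in brown cells as well, where the macrophage list did not pass (adjusted p = 0.323). In brown cells Lyz2, at the floor on 2 of 5 day 4 arrays, rose by 1.02 with the floor at the 40th percentile, and its call ended (adjusted p = 0.0740). Of cholesterol synthesis genes 4 of 15 fell in white cells and the list did not pass (adjusted p = 0.226, with 1 higher and 5 lower adjusted over the list alone). The other 15 lists did not pass, with adjusted p from 0.125 (oxidative phosphorylation, 9 higher and 1 lower of 58) to 0.960. The median, mean and test differed in sign for the glycolysis and the Wnt, BMP and TGF-beta signalling lists.

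**Figure D3:**
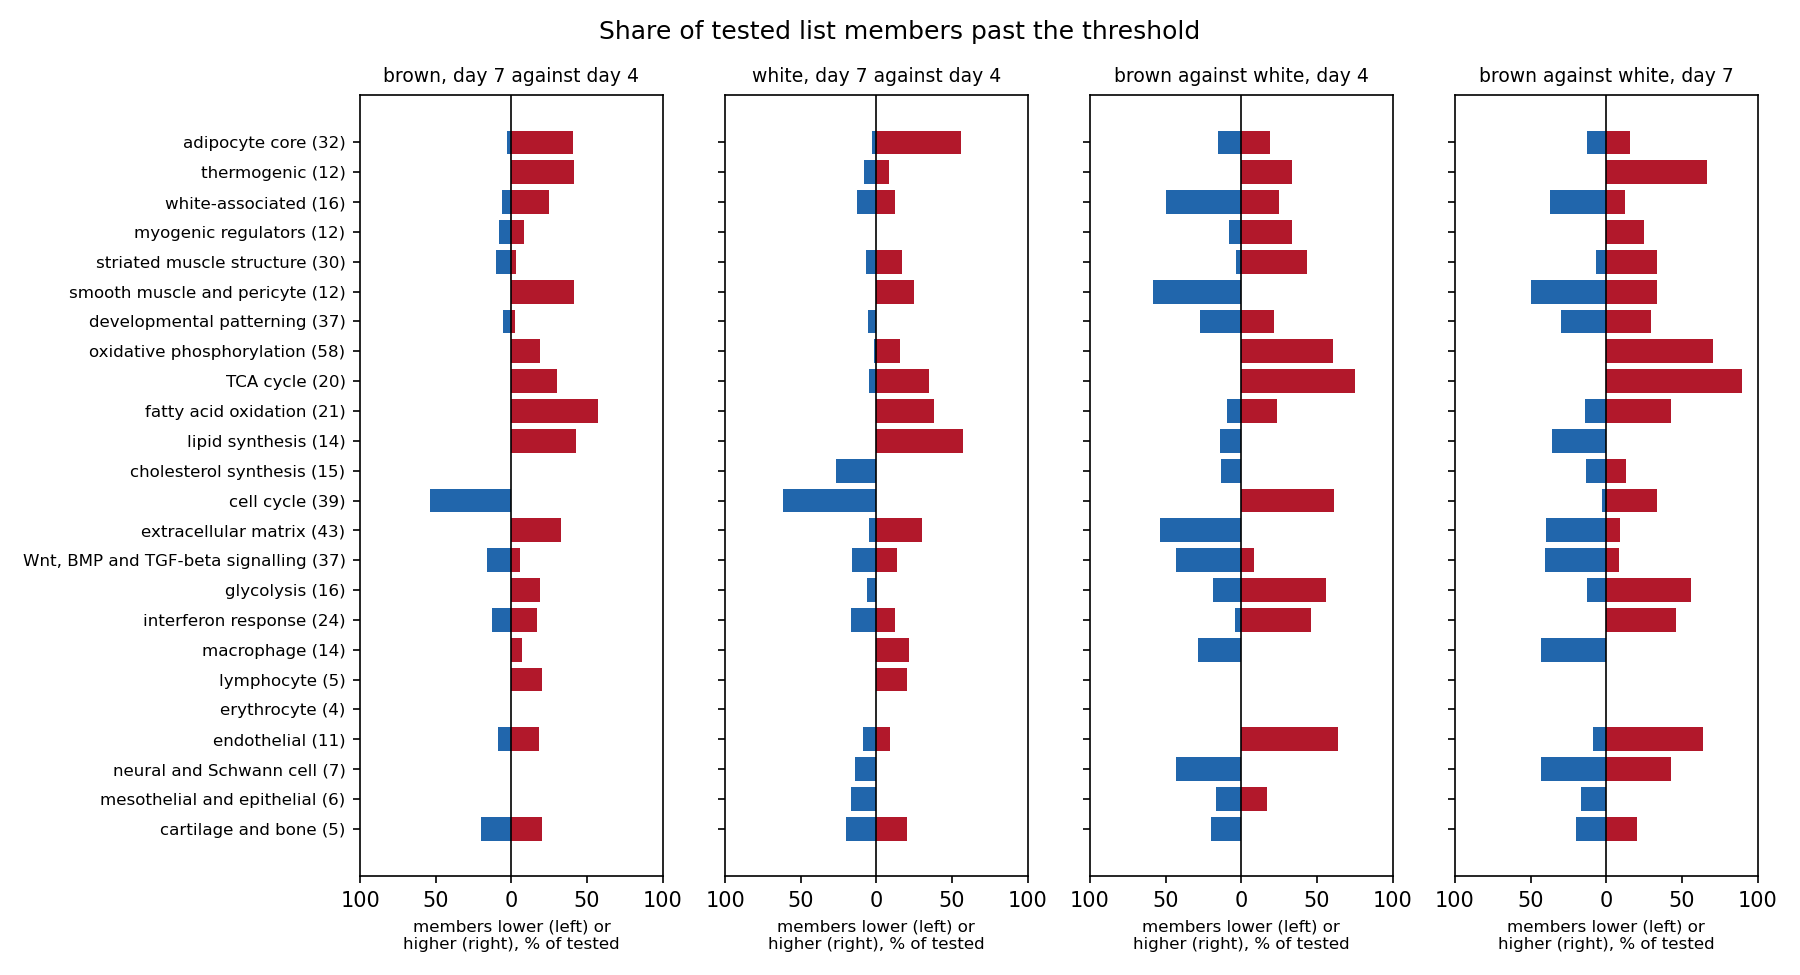
Bars show the percentage of tested members of each of the 24 gene lists (number tested in brackets) past the adjusted p threshold, higher to the right and lower to the left of 0, for the 4 comparisons of groups. Cell cycle members fell with the day in both cell types, 21 and 24 of 39, and oxidative phosphorylation members were higher in brown cells, 35 of 58 at day 4 and 41 of 58 at day 7.

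At day 4, 13 of 30 striated muscle genes were higher in brown than in white cells (camera adjusted p = 1.10e-06; 0.0163 with an estimated correlation). Tnnc1, which encodes the slow skeletal and cardiac troponin C, was at least 17.7-fold higher in brown cells, and the transcription factor gene Zic1 at least 10.98-fold higher, both at the floor on all white day 4 arrays. The homeobox gene Lhx8 was higher by 3.62 ± 0.31, the myosin light chain gene Myl1 by 3.69 ± 0.25, Acta1 by 3.55 ± 0.29 and the imprinted gene Nnat by 3.82 ± 0.50. White cells were higher for the transcription factor gene Tcf21 (brown minus white -4.83 ± 0.22), the homeobox gene Hoxa7 (-3.89 ± 0.23), the binding protein gene Igfbp3 (-5.34 ± 0.30), Igf1 (-4.75 ± 0.42) and the retinaldehyde dehydrogenase gene Aldh1a3 (-4.95 ± 0.26). In all, 1933 of 8397 probe sets differed, 909 higher and 1024 lower in brown, or 1538 of 6281 genes. At least 2-fold, 158 were higher and 422 lower. For 610 of the 8397, 597 of them called, the 5 brown and 8 white arrays did not overlap, where chance gives 0.155%. The Gapdh ratio was 0.884 in the brown and 0.943 in the white arrays, and 84 of the 85 genes past the threshold that the rule named passed with it as a covariate, all but Sc5d. As the ratio did not differ detectably between these groups, the covariate could move this comparison little, and the fit tests little.

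The highest and lowest genes here were taken only from those past the threshold whose brown and white arrays did not overlap. The remaining genes highest in brown cells at day 4 were Meox2, a homeobox gene of the muscle lineage, at 3.09 ± 0.32, Rpl39l at 3.07 ± 0.30, the troponin I gene Tnni1 at 2.57 ± 0.31 and Cldn5, a tight junction gene of endothelium, at 2.56 ± 0.48. The remaining lowest were Wnt4 at -4.20 ± 0.34, Sphk1 at -3.81 ± 0.35, Zbtb20 at -3.44 ± 0.43, Aldh1a2 at -3.31 ± 0.44 and Cck at -3.24 ± 0.42. Of the 8 white arrays, 4 lay at the floor for Lhx8, 3 for Cidea, 2 for Meox2, 1 for Nnat and 1 for Cldn5. Of the 5 brown arrays, 4 did for Aldh1a3, Wnt4, Aldh1a2, Cck and Rspo1, 3 for Tcf21, Hoxa7 and Zbtb20, and 1 for Igf1. The sizes of these differences depend on the floor. With no floor and with the floor at the 40th percentile they were 4.14 and 2.27 for Lhx8, 3.31 and 1.84 for Cidea and -5.03 and -3.46 for Tcf21. Of the panel, Cidea was higher in brown cells by 3.09 ± 0.57 (adjusted p = 0.000269), Pparg by 1.17 ± 0.20 (adjusted p = 0.00015), and Myog by 2.34 ± 0.32 (adjusted p = 5.83e-06). Cebpa was higher by 0.68 ± 0.20 (adjusted p = 0.0166), a call that ended with quantile normalization (0.0574), and Myod1 by 0.59 ± 0.18 (adjusted p = 0.0153; 0.0596 without brown day 4 array 19). Hoxc9 was lower in brown cells by the difference of -2.25 ± 0.22 and Dpt by that of -3.03 ± 0.29. Fabp4 at -0.35 ± 0.18, Adipoq at 0.38 ± 0.29 and Lep at 0.03 ± 0.24 did not pass. Zic1, Lhx8, Tcf21 and muscle genes were reported from this study, so their direction here is not independent evidence. Nor are the calls of the striated muscle list and of the white-associated list, which holds Tcf21.

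Of striated muscle genes 13 of 30 were higher in brown cells at day 4 and 1 lower (camera adjusted p = 1.10e-06; 13 and 1 adjusted over the list alone), a call that held with an estimated correlation (adjusted p = 0.0163). Abundant genes of mature muscle were not all among them. Ckm, which encodes muscle creatine kinase, was chosen after its values were seen. It measured -0.10 on the log2 scale and did not pass (adjusted p = 0.903). Its mean signal was nevertheless the higher in brown cells (59.7 ± 33.4 SD, n = 5, against 53.1 ± 12.7 SD, n = 8). Of the list, 23 of the 53 members on the array did not pass the filter. Of myogenic regulators 4 of 12 were higher and 1 lower, and the list did not pass (adjusted p = 0.0879; 4 and 1 adjusted over the list alone). White-associated genes were lower in 8 and higher in 4 of 16 cases (adjusted p = 0.00404; 8 and 4 adjusted over the list alone), and the call held with an estimated correlation (adjusted p = 0.0366). The 4 higher in brown cells, Nnat among them, were on the side opposite to the list's name. Of developmental patterning genes 8 of 37 were higher and 10 lower (adjusted p = 0.512; 8 and 10 adjusted over the list alone).

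Oxidative phosphorylation genes were higher in brown cells at day 4 in 35 of 58 cases and lower in 0 (adjusted p = 9.01e-11; 42 adjusted over the list alone, with adjusted p = 0.206 with an estimated correlation), led by the succinate dehydrogenase genes Sdhd at 0.99 ± 0.15 and Sdhb at 0.90 ± 0.17. Of TCA cycle genes 15 of 20 were higher (adjusted p = 1.38e-09; 19 adjusted over the list alone, with adjusted p = 0.147 with an estimated correlation). Idh3a at 0.77 ± 0.14 was among them. Of thermogenic genes 4 of 12 were higher (adjusted p = 0.0111; 6 adjusted over the list alone, with adjusted p = 0.213 with an estimated correlation). Cox7a1 was among them at 2.06 ± 0.49, and the list call ended without brown day 4 array 19 (adjusted p = 0.0557). Of cell cycle genes 24 of 39 were higher in brown cells (adjusted p = 1.28e-10; 27 adjusted over the list alone, with adjusted p = 0.206 with an estimated correlation). Tk1 at 1.42 ± 0.21 and Rrm2 at 1.34 ± 0.25 were among them. Of interferon response genes 11 of 24 were higher and 1 lower (adjusted p = 0.000771; 12 and 1 adjusted over the list alone, with adjusted p = 0.315 with an estimated correlation), including Ifit1 at 1.80 ± 0.37 and Usp18 at 1.65 ± 0.31.

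Extracellular matrix genes were lower in brown cells at day 4 in 23 of 43 cases (adjusted p = 9.82e-08; 23 adjusted over the list alone, with adjusted p = 0.213 with an estimated correlation), such as Dpt, Lum at -1.86 ± 0.31 and the collagen gene Col1a1 at -1.71 ± 0.22. Of Wnt, BMP and TGF-beta signalling genes 16 of 37 were lower and 3 higher (adjusted p = 5.50e-06; 18 and 3 adjusted over the list alone, with adjusted p = 0.143 with an estimated correlation). Rspo1 at -3.01 ± 0.21 and Sfrp1 at -2.31 ± 0.24 were among them. Inhbb, an activin subunit gene, was at least 6.58-fold lower, at the floor on all brown day 4 arrays. Of smooth muscle and pericyte genes 7 of 12 were lower (adjusted p = 0.000107; 7 adjusted over the list alone, with adjusted p = 0.114 with an estimated correlation). The calponin gene Cnn1 at -3.04 ± 0.37 and the kinase gene Mylk at -2.17 ± 0.12 were among them. Endothelial markers went the other way, higher in brown cells in 7 of 11 cases (adjusted p = 0.00107; 7 adjusted over the list alone, with adjusted p = 0.147 with an estimated correlation). Emcn at 1.72 ± 0.34 and Cdh5 at 1.39 ± 0.38 were among them. Glycolysis genes were higher in 9 and lower in 3 of 16 cases without passing as a list (adjusted p = 0.248; 9 and 4 adjusted over the list alone). The mesothelial and epithelial list did not pass (adjusted p = 0.260; 1 higher and 1 lower of 6), and Wt1, a transcription factor gene of mesothelium, was lower by the difference of -2.83 ± 0.20 (-1.71 with the floor at the 40th percentile). The remaining 9 lists did not pass, with adjusted p from 0.0994 (macrophage, 4 of 14 lower) to 0.735. The median, mean and test differed in sign for the adipocyte core, developmental patterning, neural and Schwann cell, and cartilage and bone lists.

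**Figure D4:**
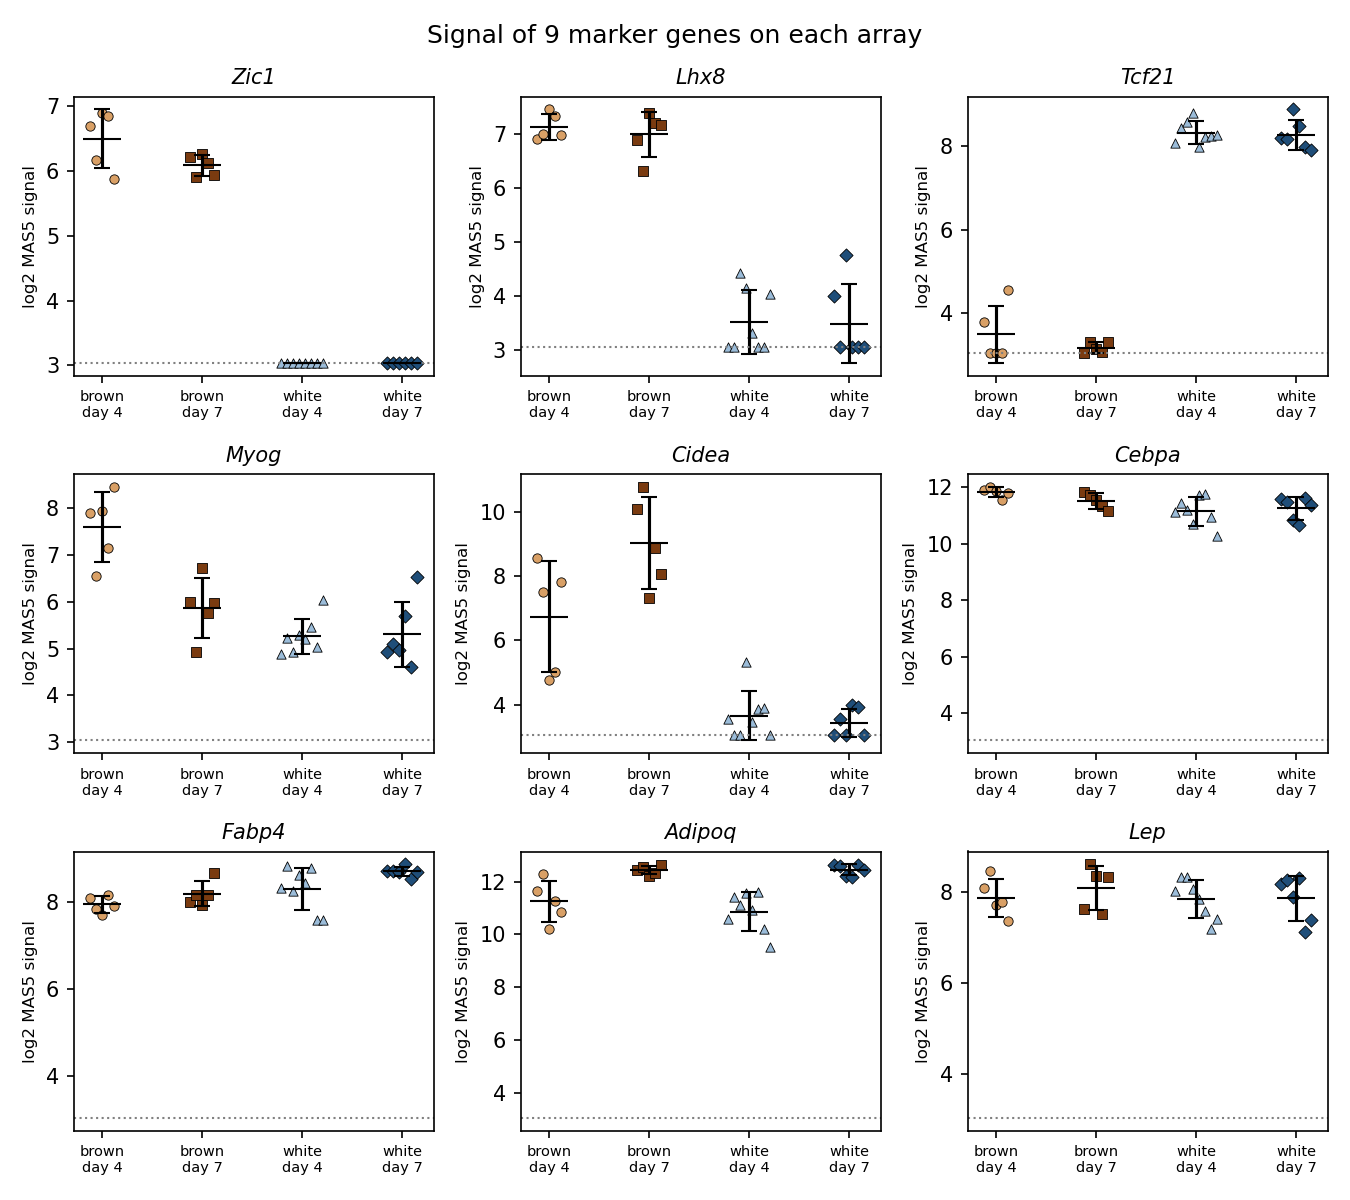
Log2 signal of 9 of the panel genes is plotted for each array by group, with the mean and SD as lines and the floor (a signal of 8.22) as a dotted line. Zic1 is at the floor on all white arrays, Tcf21 is far higher on the white arrays, and Adipoq rises with the day in both cell types.

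At day 7, 8 of 12 thermogenic, 41 of 58 oxidative phosphorylation and 7 of 11 endothelial genes were higher in brown than in white cells (camera adjusted p = 0.000124, 1.30e-16 and 2.88e-05). With an estimated correlation the adjusted p was 0.100, 0.126 and 0.100. Cidea was higher in brown cells by 5.60 ± 0.60 and Cox7a1 by 3.89 ± 0.53. Meox2 was higher by 4.03 ± 0.34, Lhx8 by 3.50 ± 0.33, and the apolipoprotein gene Apod by 3.86 ± 0.35. The endothelial genes Icam2 and Rasip1 were higher by 3.81 ± 0.31 and 3.52 ± 0.43. White cells were higher for Tcf21 (brown minus white -5.09 ± 0.23), Aldh1a3 (-4.14 ± 0.27), Zbtb20 (-4.20 ± 0.46) and Igfbp3 (-3.49 ± 0.32), and Wnt4 was at least 30.4-fold lower in brown cells, at the floor on all brown day 7 arrays. In all, 2112 of 8397 probe sets differed, 1076 higher and 1036 lower in brown, or 1598 of 6281 genes, with 283 higher and 451 lower at least 2-fold. For 1522 of the 8397, 1343 of them called, the 5 brown and 6 white arrays did not overlap, where chance gives 0.433%. The Gapdh 3' over 5' ratio, 0.889 in brown and 1.36 in white, moved with this comparison too. With it as a covariate, chosen after seeing the data, 274 probe sets passed, 264 of them among the 2112, as did 47 of the 92 genes past the threshold that the rule named. The size with the ratio was a median 0.920 times that without it across the 92, at most 0.5 times for 6 of them, and turned for 1, Nsdhl. The median standard error was 0.275 without and 0.479 with it. Cidea, Cox7a1, Meox2, Lhx8, Apod, Icam2, Rasip1, Tcf21, Aldh1a3, Zbtb20, Igfbp3 and Wnt4 passed in that fit.

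Agtr2, an angiotensin receptor gene, was at least 21.1-fold higher in brown cells at day 7, at the floor on all white day 7 arrays, and Gimap4 was higher by 3.93 ± 0.46. Zic1 was at least 8.25-fold higher, Cck at least 15.8-fold lower, and Wdr92 lower by the difference of -3.59 ± 0.23. Il1rn at 3.78 ± 0.48, Hipk2 at -3.58 ± 0.66, Cfi at -3.53 ± 0.52 and Nfib at -3.44 ± 0.41 lost their calls with the covariate, at 1.66, -1.33, -2.77 and -2.11 (adjusted p = 0.187, 0.575, 0.0895 and 0.0760). Of the 6 white arrays, 4 lay at the floor for Apod, Icam2, Il1rn, Rasip1 and Lhx8, 3 for Cidea, Meox2 and Tnnc1, 2 for Gimap4 and 1 for Tie1. Of the 5 brown arrays, 3 did for Zbtb20 and Hipk2, 2 for Aldh1a3 and 1 for Tcf21. The sizes of these differences depend on the floor. With no floor and with the floor at the 40th percentile they were 5.68 and 4.17 for Cidea, 3.93 and 2.13 for Lhx8, 4.47 and 2.38 for Apod and -5.10 and -3.41 for Tcf21. Of the panel, Pparg was higher in brown cells by 0.91 ± 0.22 (adjusted p = 0.00271), and Hoxc9 at -1.70 ± 0.23 and Dpt at -3.03 ± 0.31 were lower. Cebpa at 0.27 ± 0.22, Fabp4 at -0.51 ± 0.19 (adjusted p = 0.0503), Adipoq at -0.02 ± 0.31, Lep at 0.23 ± 0.25, Myog at 0.57 ± 0.34 and Myod1 at 0.15 ± 0.19 did not pass. Ucp1 did not pass the filter and was not tested. The signal of its brighter probe set was 65.4 ± 50.9 (SD, n = 5) in brown and 10.7 ± 6.77 (SD, n = 6) in white cells at day 7, and 19.04 ± 15.5 (SD, n = 5) and 6.68 ± 4.86 (SD, n = 8) at day 4. The related probe set of Ucp1 gave 18.4 ± 7.03 (SD, n = 5) and 16.8 ± 7.43 (SD, n = 6) at day 7. On day 7 arrays 07, 08, 11, 12 and 22 the brighter probe set of Ucp1 measured 113, 125, 17.4, 19.04 and 53.1. Ppargc1a, Dio2 and Myf5 had no group mean above 19.7.

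Of thermogenic genes 8 of 12 were higher in brown cells at day 7 and 0 lower (camera adjusted p = 0.000124; 8 adjusted over the list alone, with adjusted p = 0.100 with an estimated correlation). Oxidative phosphorylation genes were higher in 41 of 58 cases and lower in 0 (adjusted p = 1.30e-16; 46 adjusted over the list alone, with adjusted p = 0.126 with an estimated correlation). Sdhd at 1.51 ± 0.16, Ndufb8 at 1.36 ± 0.19 and Uqcrc1 at 1.25 ± 0.17 were among them. Of TCA cycle genes 18 of 20 were higher (adjusted p = 2.90e-12; 19 adjusted over the list alone, with adjusted p = 0.100 with an estimated correlation). Idh2 at 1.15 ± 0.14 was among them. Of glycolysis genes 9 of 16 were higher and 2 lower (adjusted p = 0.00805; 9 and 2 adjusted over the list alone, with adjusted p = 0.152 with an estimated correlation). Pgk1 was higher by 0.85 ± 0.15 and lost its call with the Gapdh ratio as a covariate (0.148). Of cell cycle genes 13 of 39 were higher and 1 lower (adjusted p = 6.25e-06; 15 and 1 adjusted over the list alone, with adjusted p = 0.354 with an estimated correlation). The cyclin gene Ccnd1 at 1.23 ± 0.19 was among them. Of interferon response genes 11 of 24 were higher (adjusted p = 0.000129; 14 adjusted over the list alone, with adjusted p = 0.252 with an estimated correlation), a list call that ended with the Gapdh ratio as a covariate (adjusted p = 0.122). Of fatty acid oxidation genes 9 of 21 were higher and 3 lower (adjusted p = 0.0301; 9 and 4 adjusted over the list alone, with adjusted p = 0.521 with an estimated correlation). Hadhb at 1.48 ± 0.19 was among them. The fatty acid oxidation call ended with quantile normalization (adjusted p = 0.0557), no filter (0.0585), the stricter filter (0.0515) or the mean of probe sets (0.0519). It also ended without arrays 45 and 51 (0.0544), and without brown day 7 array 07, 08 or 22 (0.0665, 0.0560 and 0.0700) or white day 7 array 39 or 40 (0.0602 and 0.0769).

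Extracellular matrix genes were lower in brown cells at day 7 in 17 and higher in 4 of 43 cases (adjusted p = 4.82e-05; 18 and 4 adjusted over the list alone, with adjusted p = 0.357 with an estimated correlation). The metalloproteinase gene Mmp14 at -1.74 ± 0.20 was among them. Of Wnt, BMP and TGF-beta signalling genes 15 of 37 were lower and 3 higher (adjusted p = 4.40e-05; 17 and 3 adjusted over the list alone, with adjusted p = 0.126 with an estimated correlation). Sfrp1 at -3.07 ± 0.26 was among them. Rspo1 was at least 9.03-fold lower, at the floor on all brown day 7 arrays. Of smooth muscle and pericyte genes 6 of 12 were lower and 4 higher (adjusted p = 0.00805; 8 and 4 adjusted over the list alone, with adjusted p = 0.188 with an estimated correlation). Cnn1 at -2.88 ± 0.39 was among them. White-associated genes were lower in 6 and higher in 2 of 16 cases (adjusted p = 0.0158; 6 and 2 adjusted over the list alone, with adjusted p = 0.100 with an estimated correlation). The median of that list was 0.12 and its mean -0.75, so that they differed in sign. Of lipid synthesis genes 5 of 14 were lower (adjusted p = 0.0381; 5 adjusted over the list alone, with adjusted p = 0.491 with an estimated correlation). That call ended with the covariate (adjusted p = 0.698) and without brown day 7 array 11 or 22 (0.0755 and 0.137) or white day 7 array 43 or 44 (0.106 and 0.0665). Its leading members, the acyltransferase gene Gpam at -1.48 ± 0.25 and Me1 at -1.41 ± 0.24, lost their calls with the covariate, at -0.85 and -1.12 (adjusted p = 0.317 and 0.151).

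Markers of other cell types also differed at day 7. Endothelial markers were higher in brown cells in 7 of 11 cases and lower in 1 (adjusted p = 2.88e-05; 7 and 2 adjusted over the list alone, with adjusted p = 0.100 with an estimated correlation). Emcn at 2.78 ± 0.36, Tie1 at 2.68 ± 0.27, the cadherin gene Cdh5 at 2.59 ± 0.41 and Cd34 at 2.09 ± 0.29 were among them, and Cdh5 was 3.94 with the Gapdh ratio as a covariate. Pecam1 at -0.32 and Kdr at 0.69, chosen after their values were seen, did not pass. Striated muscle genes were higher in 10 and lower in 2 of 30 cases (adjusted p = 0.00805; 12 and 3 adjusted over the list alone, with adjusted p = 0.126 with an estimated correlation). Tnnc1 at 3.04 ± 0.26 and Myl1 at 2.67 ± 0.27 were among them. Macrophage markers were lower in 6 of 14 cases (adjusted p = 0.00805; 6 adjusted over the list alone, with adjusted p = 0.381 with an estimated correlation). Lyz2 was lower by the difference of -1.56 ± 0.46 and lost its call with the Gapdh ratio as a covariate (0.204). Cartilage and bone genes did not pass as a list (adjusted p = 0.813; 1 higher and 1 lower of 5), and the phosphatase gene Alpl was lower by the difference of -2.23 ± 0.33. Nor did the neural and Schwann cell (adjusted p = 0.810; 3 and 3 of 7), mesothelial and epithelial (0.5262; 1 lower of 6), lymphocyte (0.813; 0 of 5), erythrocyte (0.813; 0 of 4), myogenic regulator (0.0694; 3 higher of 12), developmental patterning (0.5262; 11 and 11 of 37), cholesterol synthesis (0.848; 2 and 2 of 15) or adipocyte core lists (0.747; 5 higher and 4 lower of 32). The median, mean and test also differed in sign for the mesothelial and epithelial list.

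Brown and white cells changed much alike between the days. Of the 407 genes that rose in brown cells and the 567 that rose in white cells, 210 rose in both, against 36.7 for independent lists (Fisher's exact test p = 4.04e-122). Of the 409 and 656 that fell, 268 fell in both, against 42.7 (Fisher's exact test p = 4.99e-180). Only 2 genes were called in opposite directions, chosen here after their values were seen: Acta1 (-1.55 ± 0.32 in brown and 1.10 ± 0.28 in white) and Gng11 (0.52 ± 0.17 and -0.54 ± 0.14). The white calls of Acta1 (1.70, adjusted p = 0.0855) and Gng11 (-0.45, 0.491) ended with the Gapdh ratio as a covariate. Across 6281 genes, which are not independent replicates, the changes correlated with a Pearson r of 0.64 and a Spearman rho of 0.61. The differences between brown and white cells at day 4 and day 7 shared 471 genes higher in brown, against 96.5 for independent lists (Fisher's exact test p = 5.52e-283), and 495 lower, against 98.8 (p = 7.21e-310; r = 0.78, rho = 0.72 across genes). The glutathione peroxidase gene Gpx3, also chosen after its values were seen, was called in opposite directions (-0.97 ± 0.19 at day 4 and 0.59 ± 0.20 at day 7), and its day 7 call ended with the covariate (0.0036, adjusted p = 0.997). The comparisons of each pair share no arrays, but both use the same estimate of the spread of each probe set. Fisher's exact test also takes genes as independent, so its p-values here do not measure the strength of the overlap.

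The change between days differed between brown and white cells for 18 probe sets, 14 more positive and 4 more negative in brown, and 670 had an unadjusted p under 0.05. Of the 6281 genes, 12 passed by the probe set that represents them. Acta1 (brown minus white -2.64 ± 0.42) fell in brown and rose in white cells. Cyp2e1, a cytochrome P450 gene, rose by 2.003 ± 0.22 in white cells and measured -0.22 ± 0.26 in brown cells, a difference of -2.22 ± 0.34 (adjusted p = 0.00126). Ahsg rose more in brown cells, by at least 2.18 on the log2 scale, being at the floor on all brown day 4 arrays. The difference for Fam167b was 2.81 ± 0.41. Fam167b was at the floor on all brown day 4 and white day 7 arrays and on 7 of 8 white day 4 arrays. Its change in white cells was therefore not measured, and the value is no bound. Gpx3 rose by 1.40 ± 0.21 in brown cells and measured -0.16 ± 0.18 in white cells (difference 1.56 ± 0.28, adjusted p = 0.00943), a call lost with the Gapdh ratio as a covariate (0.658). The Ahsg call was lost with the floor at the 40th percentile (0.747). Apod (2.22 ± 0.48), Rgs16 (1.28 ± 0.28) and Amy1 (-2.10 ± 0.46) had an adjusted p of 0.0479 each and missed the threshold in 21, 18 and 21 of the 24 fits that left out an array (adjusted p at most 0.165, 0.125 and 0.125). They also missed it with no floor (0.263, 0.0620 and 0.678) and with the Gapdh ratio (0.0915, 0.335 and 0.647). Apod and Rgs16 missed it with quantile normalization (0.0568 and 0.0628), no filter (0.0782 and 0.111) and the stricter filter (0.147 and 0.0581). Rgs16 missed it without trend (0.0747) and Amy1 without arrays 45 and 51 (0.0930). Apod passed without brown day 4 array 06, white day 4 array 51 or white day 7 array 35. Rgs16 passed without any 1 of those or brown day 4 array 10, white day 4 array 41 or white day 7 array 39. Amy1 passed without white day 4 array 33 or 34 or white day 7 array 40. Amy1 was at the floor on all brown day 4 arrays and on 5 of 8 white day 4 arrays, so that the size of its difference depends on the floor. So does that of Apod, at the floor on 3 of 8 white day 4 and 4 of 6 white day 7 arrays. Cidea (2.51 ± 0.83, adjusted p = 0.285) and Myog (-1.77 ± 0.47, adjusted p = 0.135) did not pass. The count of probe sets was 7, 9, 10 and 8 without brown day 4 array 05, 09, 10 and 19, and 5, 6, 5, 4 and 10 without brown day 7 array 07, 08, 11, 12 and 22. It was 11, 9, 9, 7 and 8 without white day 4 array 33, 34, 37, 42 and 45, and 8, 11 and 8 without white day 7 array 36, 39 and 43.

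Of the lists, striated muscle genes changed differently between days in brown and white cells (1 of 30 members past the threshold, Acta1; median difference -0.40, camera adjusted p = 0.000164; 7 adjusted over the list alone, with adjusted p = 0.0553 with an estimated correlation). Oxidative phosphorylation (median 0.20, adjusted p = 0.00039, with adjusted p = 0.815 with an estimated correlation) and TCA cycle genes (0.19, adjusted p = 0.00821, with adjusted p = 0.815 with an estimated correlation) changed more upward in brown cells, with 0 members past the threshold and 0 adjusted over the list alone. So did endothelial (0.90, adjusted p = 0.00125; 3 and 1 adjusted over the list alone, with adjusted p = 0.321 with an estimated correlation), thermogenic (0.39, adjusted p = 0.0110; 0 adjusted over the list alone, with adjusted p = 0.429 with an estimated correlation) and glycolysis genes (0.17, adjusted p = 0.0318; 1 adjusted over the list alone, with adjusted p = 0.429 with an estimated correlation). Cell cycle genes changed more downward (-0.22, adjusted p = 0.0465; 0 adjusted over the list alone, with adjusted p = 0.815 with an estimated correlation). Without brown day 4 array 10 or brown day 7 array 08 the TCA cycle, thermogenic, glycolysis and cell cycle calls ended (adjusted p = 0.0793 for each without array 10, and 0.114, 0.114, 0.122 and 0.346 without array 08). The TCA cycle call also ended without array 07, 39 or 40 (0.0744, 0.0692 and 0.0645) and the thermogenic call without array 40 (0.0522). The glycolysis call ended without array 05, 07, 22, 42, 35, 39 or 40 (0.0517, 0.102, 0.0586, 0.0647, 0.0744, 0.0692 and 0.0522). The cell cycle call ended without array 05, 09, 12, 34, 37, 42, 51, 35, 39 or 43 (0.112, 0.230, 0.273, 0.134, 0.0895, 0.0653, 0.163, 0.191, 0.274 and 0.409). Its direction turned upward with the Gapdh ratio as a covariate (adjusted p = 0.0547). It also ended with quantile normalization (0.197), no floor (0.0504), no filter (0.0763), the stricter filter (0.0552) and without arrays 45 and 51 (0.103). The thermogenic call ended with no filter (0.106) and with the mean of probe sets (0.123). The glycolysis call ended with quantile normalization (0.0582), the stricter filter (0.0552), the mean of probe sets (0.0710), the Gapdh ratio (0.139) and without arrays 45 and 51 (0.0675). By fry, which tests whether a list moves one way on balance, only the striated muscle list passed (adjusted p = 0.0162). The other 17 lists did not pass, with adjusted p from 0.0639 (fatty acid oxidation) to 0.957. The median, mean and test differed in sign for the adipocyte core, white-associated, developmental patterning and erythrocyte lists.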

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

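The tests with the Gapdh ratio as a covariate were added after seeing the data. The requirement that the ratio itself differ between the groups tested, and the tests of the covariation of list members within the brown groups, with the requirement that it hold without any 1 brown array, were chosen only after the results were seen. Other assignments of the same arrays to groups were drawn at random, 100 per comparison with the real one included. Only 1 of the 100, the real one, gave as many probe sets for brown day 7 against day 4 (1013, highest other 551), white day 7 against day 4 (1595, highest other 262), brown against white at day 4 (1933, highest other 1066), brown against white at day 7 (2112, highest other 1069) and the difference of changes (18, highest other 2). So many calls would thus be rare in all 5 if the arrays were independent of each other. The labels do not say whether they were, so chance differences between animals or cultures cannot be excluded. For the difference of changes, assignments were drawn within each cell type, after additive effects of cell type and day had been taken out. Between 126 and 756756 assignments were possible.

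Single arrays were flagged as far from the rest of their group in 7 of 184 groups of values tested, where chance gives about 1 in 20, or 9.2. In white day 4, Ucp1 signal was 18.5 on array 51 (others 3.54 to 6.32), Cidea 39.9 on array 38 (others 4.29 to 14.9) and Ppargc1a 11.3 on array 37 (others 1.07 to 8.60). These signals were tested as log2 values with the floor. All other arrays lay at the floor for Ucp1 and most did for Ppargc1a. The Ppargc1a flag rests on the floor rather than on the signals printed. In brown day 4, array 19 had the highest mean log2 signal of the myogenic regulators, 6.37 (others 5.87 to 6.01), and of the endothelial list, 6.87 (others 6.29 to 6.45). In white day 7, array 43 had a macrophage list mean of 5.30 (others 6.04 to 6.46). In brown day 7, array 07 had a mesothelial and epithelial list mean of 4.32 (others 4.88 to 5.03).

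Between days, 12 genes passed the test of the difference between the changes in the 2 cell types (log2, brown minus white). The rule for named genes took 8 of them: Fam167b, Apod at 2.22, Ahsg at 2.18, Gpx3 at 1.56, Rgs16 at 1.28, Acta1 at -2.64, Cyp2e1 at -2.22 and Amy1 at -2.10. The other 4, chosen after their values were seen, were Ctsh at 1.24 ± 0.25, Pdia6 at 1.20 ± 0.26, Kng1 at 1.07 ± 0.22 and Gng11 at 1.06 ± 0.22. Their adjusted p was 0.0386, 0.0479, 0.0393 and 0.0423, close to the threshold. Whether these 4 calls hold in the alternative fits was not examined. The Ahsg value is a lower bound. For Fam167b 7 of 8 white day 4 and all 6 white day 7 arrays lay at the floor, so its change in white cells was not measured, and its fitted 2.81 is neither a size nor a bound of the difference. The Amy1 and Apod values depend on the floor, where 5 and 3 of the 8 white day 4 arrays lay. By camera, 7 lists passed the same test, with median differences of 0.39 (thermogenic), -0.40 (striated muscle), 0.20 (oxidative phosphorylation), 0.19 (TCA cycle), -0.22 (cell cycle), 0.17 (glycolysis) and 0.90 (endothelial). With an estimated correlation 0 of the 7 passed, with adjusted p from 0.0553 to 0.815. The cell cycle list turned upward with the Gapdh ratio as a covariate (adjusted p = 0.0547).

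Respiratory chain and TCA cycle genes were higher in brown cells at day 7, where the white arrays had the higher 3' over 5' ratios. With the Gapdh ratio in the fit the median difference of the 55 called members was 1.083 times that without it (0.82 to 0.89), and 0.922 to 1.28 times without any 1 array. The ratios of brown and white arrays did not overlap at day 7, so this fit extrapolates and alone cannot decide. Most tested members of both lists were already higher in brown cells at day 4, where the ratio did not differ detectably. That argues against RNA integrity as the whole cause. Only 17 of the 55 kept their calls. The median difference did not shrink, while the median standard error grew from 0.161 to 0.281. A greater mitochondrial content of the brown cells and handling that differed between the cell types both stay open as hypotheses, and neither was tested.

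Endothelial markers were higher in brown cells at day 7. With the Gapdh ratio in the fit the median difference of the 7 called members was 0.9793 times that without it (2.09 to 2.04, and 0.915 to 1.15 times without any 1 array). The ratios of brown and white arrays did not overlap at day 7, so this fit extrapolates and alone cannot decide. The same members were already higher in brown cells at day 4, where the ratio did not differ detectably. That argues against RNA integrity as the whole cause. RNA of endothelial cells in the brown cultures is a candidate source: the 11 tested members varied together within the brown groups, with a mean correlation of 0.2149 against a 95th percentile of 0.110 in 1000 random lists, and 0.125 against 0.112 without brown day 4 array 19. Signals in brown cells at days 4 and 7 were 132 and 301 for Cdh5 and 120 and 217 for Emcn. But Pecam1 measured 53.1 and 57.3 against 65.9 and 74.5 in white cells, and Flt1 was lower in brown cells at day 7 (-1.22). Pecam1 and Flt1 were chosen here after their values were seen. A programme that varied within the brown cells themselves would give the same covariation and stays open.

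Striated muscle genes were higher in brown cells at day 4. With the Gapdh ratio in the fit the median difference of the 13 called members was 1.006 times that without it (0.961 to 1.02 times without any 1 array). The ratio itself differed little between brown and white at day 4 (0.884 and 0.943, exact permutation p = 0.277), so this test could not show an effect of RNA integrity. The actin ratio did not differ detectably either (1.47 and 1.56, exact permutation p = 0.328, adjusted 0.404). Neither ratio thus showed the difference in RNA integrity that this explanation needs, though the ratios cannot exclude one. Muscle cells in the brown cultures and a muscle-like programme of the brown cells cannot be told apart: the members varied together within the brown groups (mean correlation 0.146 against a 95th percentile of 0.0920), but not without brown day 4 array 09 (0.0409 against 0.0975) or array 10 (0.0867 against 0.101). Signals in brown and white cells at day 4 were 583 and 53.5 for Acta1 and 439 and 83.4 for Tnni1. They were 59.7 and 53.1 for Ckm, chosen after its values were seen, whose log2 difference was -0.10. No sort or gate is given in the sources used here.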

How the results depend on the processing

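The Gapdh ratio as a covariate and the removal of white day 4 arrays 45 and 51 were chosen after seeing the data, and the other alternatives were planned. The labels do not pair the arrays: no array number occurs in more than 1 group, and nothing says that adjacent numbers share a culture or a day. With runs of adjacent numbers as a random block, 5 of which hold both days of a cell type, the counts were 1384 and 1880 between days in brown and white cells and 1450 and 1476 between cell types at days 4 and 7. Of the named genes 5 of 85 at day 4 and 7 of 92 at day 7 missed the threshold in that fit, and 0 of 78 did between days in either cell type. The counts of changed probe sets, 1013 and 1595 between days in brown and white cells and 1933 and 2112 between cell types at days 4 and 7, were 336, 328, 580 and 734 at a fold of at least 2, by construction. The brown count was 1666 with array weights. With the Gapdh ratio the white count was 37 and the day 7 count 274. Without arrays 45 and 51, and so with fewer arrays, the white count was 1054. The difference of changes, 18, was 10 with no floor, 35 with the higher floor, 10 with no filter, 8 with the stricter filter, 11 without trend, 44 with array weights, 36 with number runs as a block and 5 with the Gapdh ratio. Leaving out 1 array gave 668 to 1165 in brown cells, 1127 to 1909 in white cells, 1551 to 2149 at day 4, 1710 to 2261 at day 7 and 4 to 23 for the difference of changes. Lists past the threshold, 9, 8, 11, 15 and 7, were 0, 0, 2, 0 and 0 with an estimated correlation. By fry they were 12, 7, 14 and 17 in the comparisons of groups and 1 for the difference of changes. For that difference they were 3 to 9 when 1 array was left out. Directions turned only with the Gapdh ratio: the cell cycle list in the difference of changes (adjusted p = 0.0547), Nsdhl and Mvd in white cells (log2 difference 0.21 and 0.00016) and Nsdhl at day 7 (-0.26). Of 341 named gene results, 222 stayed past the threshold in the same direction with the Gapdh ratio, 330 with quantile normalization, 319 with the higher floor and 285 in every fit that left out an array. Where no construction is named the cause was not tested.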

Other observations

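The lists here, of plasma proteins, the insulin-like growth factor system, retinoid metabolism and imprinted genes, and all of their tests were chosen only after the results were seen, so their directions are not independent evidence. Their p-values were adjusted over 20 tests, all of these lists in all contrasts together. They are thus not comparable with those of the fixed lists, which were adjusted within a contrast. Acute phase and plasma protein genes rose between days in both cell types. In brown cells 10 of 16 rose (camera adjusted p = 1.29e-12; 0.00647 with an estimated correlation) and in white cells 12 of 16 (6.42e-09; 0.0188 with an estimated correlation). Serpina3n, a protease inhibitor gene, rose by 2.07 ± 0.26 in brown and 0.95 ± 0.22 in white cells, and was lower in brown than white cells at day 4 (-2.20 ± 0.23). Saa3, a serum amyloid gene, rose by 1.89 ± 0.27 in brown cells. At day 4, 6 of 16 were lower in brown cells (adjusted p = 6.39e-05; 0.0955 with an estimated correlation), and at day 7 again 6 (0.00524; 0.250 with an estimated correlation).

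Genes that make or handle retinoic acid were lower in brown cells, 4 of 6 at day 4 with 1 higher (adjusted p = 0.000215; 0.00612 with an estimated correlation) and 4 of 6 at day 7 (6.28e-05; 0.00459 with an estimated correlation). Besides Aldh1a3 these included Aldh1a1 (-1.80 ± 0.20 at day 4 and -2.14 ± 0.22 at day 7) and the retinal reductase gene Dhrs3 (-2.52 ± 0.17 and -3.31 ± 0.18). The list did not pass between days in brown cells (adjusted p = 0.277) or in white cells (0.675). Of the insulin-like growth factor system, 4 of 11 genes were lower and 1 higher in brown cells at day 4 (adjusted p = 5.80e-05; 0.0149 with an estimated correlation), and 6 lower and 1 higher at day 7 (0.000215; 0.0210 with an estimated correlation). Igfbp4 was lower in brown cells by the differences of -2.04 ± 0.12 and -1.41 ± 0.12, and Igf2 was higher, by 0.95 ± 0.20 and 1.10 ± 0.21. In this list 6 genes rose between days in brown cells (adjusted p = 0.000215; 0.0210 with an estimated correlation) and 4 in white cells (0.00964; 0.104 with an estimated correlation). The imprinted list did not pass in these 4 comparisons (adjusted p = 0.804, 0.490, 0.277 and 0.674 in brown cells, white cells, day 4 and day 7). For the difference of changes the plasma protein list passed (adjusted p = 0.00524; 0.250 with an estimated correlation), and the others did not (0.0897 to 0.358).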
